A study of Mus musculus with 24 samples.

How the data were processed

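Gene expression was measured on microarrays in sensory tissue of the mouse inner ear, from animals with a conditional knockout of Rb1 (named Pou4f3-Rb1 cKO in the labels, cKO from here on) and from littermate controls. Rb1 encodes the retinoblastoma protein, a pocket protein that holds E2F transcription factors in check, and Pou4f3 is a transcription factor gene of hair cells. The settings were the utricle at 2 months, the utricle at postnatal day 6 (P6) and the cochlea at P6. Tissue was dissected in culture medium, kept in an RNA preservative and extracted on spin columns, and biotin-labelled cRNA was made with a small-sample protocol of the array maker, per the labels' protocols. Each setting had 1 pool of RNA per genotype, which makes 6 pools, and each pool was hybridised as technical duplicates on 2 Affymetrix array types, called a and b here after the suffix in the labels, so that each table held 12 arrays. The duplicates were repeats of the same pooled RNA. A p-value therefore measures technical spread, and differences between animals or between pools of animals do not enter it, except in the comparison over pool pairs.

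The deposited values were linear intensity values, 1 per probe set and array, made by the authors with the MAS5 algorithm, per the submitters' processing notes. The version, the scaling target and detection calls are not given in the sources used here. The values had been scaled between arrays before deposit: array medians lay between 208 and 223 on type a and between 128 and 136 on type b, a range of 0.0984 and 0.0862 on the log2 scale. Type a held 22690 probe sets and type b 22575, of which 64 on each were hybridisation and labelling controls. Probe sets were named through a platform annotation table supplied with the data, which can be old. On type a, 20393 had 1 gene symbol, 691 had several and 1606 had none; on type b the numbers were 14674, 245 and 7656. Of the single-gene probe sets, 20364 and 14499 matched a current mouse gene table, which gave the symbols used here. Probe sets with several symbols or none stayed in the fits and were not named. No genome was used here, so the place of a probe set within its transcript was not checked. The number of arrays limits the precision.

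Signals were raised to at least 1 (97 values on type a and 100 on type b were lower), converted to log2 and kept on the deposited scale, because array medians lay within the limit of 0.5 log2 set in advance. Control probe sets and the dimmest probe sets, those under the 40th percentile of mean log2 signal (a signal of 167 on type a and 110 on type b), were left out, which left 13576 and 13507 probe sets. These covered 13450 genes. Each table was fitted by itself in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with lmFit and eBayes with an intensity trend, over its 12 arrays with a mean for each pool, so that all pools shared 1 estimate of the spread for a probe set. The comparisons were cKO against control in each of the 3 settings, the difference of that effect between P6 utricle and P6 cochlea and between 2-month and P6 utricle, 2-month against P6 control utricle, and P6 control cochlea against P6 control utricle. P-values were adjusted within a table by the Benjamini-Hochberg method at a threshold of 0.05, and counts are of probe sets summed over both tables. For the effect over pool pairs the duplicates were averaged and the 6 pool means fitted with a block for tissue and age, which leaves the spread between pool pairs as the error.

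For statements on genes, 1 tested probe set stood for each gene, the brightest on type a or, failing that, on type b. The genes named were Rb1, then for each setting the 8 highest and 8 lowest in log2 fold change among probe sets past the threshold whose cKO arrays both lay on the same side of both control arrays and whose brighter group reached the median signal of its table. To these were added up to 4 passing members of each gene list with the largest change, or the 1 or 2 with the largest change where none passed. For age and tissue the 5 highest and 5 lowest were named, for each difference of effects the 4 largest each way, and for pool pairs the 5 highest and 5 lowest by unadjusted p. The design, this rule, the alternatives and 20 gene lists were fixed before the data were examined. The lists were hair cell; G1/S and DNA replication (E2F target type); G2/M and mitosis; pocket proteins, E2Fs, cyclins D and CDK inhibitors; p53 response, DNA damage and apoptosis; supporting cell and Notch; otoconia, dark cell, stria and melanocyte; neuron; Schwann cell and myelin; fibrocyte and mesenchyme; bone and cartilage; skeletal muscle; erythroid; myeloid and lymphoid immune; endothelium and pericyte; brain (glia and cerebellum); oral and middle ear epithelium; immediate early and stress; interferon response; and sex chromosome. Lists with at least 5 tested members on type a were tested with camera at its preset correlation between genes, and again with an estimated correlation, adjusted over the lists of a comparison. List medians over both array types were also set against 10000 random lists matched on mean signal.

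The fit was tested on simulated type a data with 13576 probe sets, drawn from the pool means and spreads, with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. At 2 months it recovered 2.99%, 95.5% and 100% of these. In the P6 utricle it recovered 20.9%, 89.6% and 98.5%, in the P6 cochlea 16.4%, 85.1% and 100%, and over pool pairs 14.9%, 94% and 98.5%. Among 13376 unchanged genes it called 1 at 2 months, 29 in the P6 utricle, 33 in the P6 cochlea and 10 over pool pairs. The P6 numbers exceed 5% of the calls made there, since 1 spread is shared although duplicates of the 2-month pools differed less (SD of log2 signal 0.0966 on type a and 0.0662 on type b) than those of the P6 pools (0.22 and 0.181). Calls at 2 months are therefore few relative to fits that let the spread differ. Those at P6 are many only relative to such fits without a block for the replicate number. With only the P6 arrays and that block the totals were 1050 in the utricle and 780 in the cochlea, against 1103 and 882. In the simulation the variance of each gene was averaged with that of genes of like signal, so it varied less between genes than in the data. Its noise was drawn independently for each array, whereas P6 arrays of the same number deviated together in the type a data (correlations 0.299 to 0.675). The simulated numbers at P6 thus need not hold for the data. Over real pool pairs, limma left Mki67 (1.65 log2), Mcm6 (1.56) and Igfbp3 (1.43) at adjusted p = 0.429. The simulated shares over pool pairs are thus no measure of what the real fit can find.

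The alternatives were quantile normalization, centring on array medians, no filter and a filter at the 60th percentile, a pseudocount at the 20th percentile of signal (94.2 on type a and 67.2 on type b), no intensity trend, a fold of at least 2, the replicate number as a block, only the arrays compared, and each array left out in turn. For pool pairs, each pair was left out, the block was dropped, and pool was fitted as a random block. Detection calls are not given in the sources used here, so a group below that 20th percentile was not taken as shown to be above background. A fold against it is given as at least the brighter group over the percentile (means of log2 signal), a bound chosen after the values were seen, while the naming rule ranks fitted values. This bound makes no allowance for error and holds for the deposited scale alone. The pseudocount shrinks folds and can give less, as for Gfi1 in the P6 cochlea (1.59 log2, against a bound of 2.3). Fits of the P6 arrays alone, with and without the replicate block, array weights by age, and a replicate block within the 2-month arrays were added after seeing the data. The estimates of tissue mixing were made in R, and the figures with Python 3.11.15 and matplotlib 3.10.9. The 100 probe sets present on both array types were tested on each, and no comparison was made between the 2 tables.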

Results

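The data compared sensory tissue of cKO mice with that of littermate controls in the 2-month utricle, the P6 utricle and the P6 cochlea, on 12 arrays of each type and with 13576 and 13507 probe sets tested. Technical duplicates of a pool correlated at 0.9326 to 0.9964 over probe sets. The SD between duplicates was 0.0966 log2 at 2 months and 0.22 at P6 on type a, and 0.0662 and 0.181 on type b. The actin 3'/5' signal ratio, a measure that rises as RNA breaks down and also moves with labelling, was 2.87 and 3 in the duplicates of the 2-month control utricle and 2.51 and 2.38 in cKO (type a). In the P6 utricle it was 3.50 and 1.64 in control and 4.26 and 2.09 in cKO, and in the P6 cochlea 3.01 and 2.19 in control and 3.85 and 3.04 in cKO. The cKO pools thus had the higher ratio at P6, by 0.353 log2 in the utricle and 0.348 in the cochlea (mean of both array types), and the lower at 2 months.

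The first question was whether the targeted transcript was lower in the cKO pools. Rb1, the gene for the retinoblastoma protein, fell 2.68-fold in the P6 utricle, from a signal of 824 ± 276 in control to 300 ± 44.4 in cKO (mean ± SD of 2 technical duplicates, SE of the log2 fold change 0.216, adjusted p = 0.00565). In the P6 cochlea the signal was 559 ± 6.97 in control and 306 ± 58.2 in cKO (log2 fold change -0.88, adjusted p = 0.0507), and in the 2-month utricle 534 ± 48.6 and 430 ± 2.86 (-0.31, adjusted p = 0.845). For the P6 cochlea the limma fit with the replicate block gave adjusted p = 0.0461, and that of only the P6 arrays 0.175. The call in the P6 utricle was lost without the first cKO array (adjusted p = 0.0547) and with only the arrays compared (0.0924), while the P6 cochlea passed with quantile normalization (adjusted p = 0.0417) and with the filter at the 60th percentile (0.0487). Whether this probe set lies in the deleted part of the gene is not given in the sources used here, so its signal is a partial check of the labels, and other cells of the tissue also transcribe the gene.

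In the 2-month utricle, 15 of 13450 genes rose and 18 fell in cKO. Igfbp3, whose product binds insulin-like growth factors, rose 3.01-fold, from 443 ± 12.7 to 1334 ± 103 (mean ± SD of 2 technical duplicates, SE 0.149 log2, adjusted p = 0.00488). Pomc, the precursor gene of corticotropin and melanocortins, rose 2.32-fold, from 317 ± 8.19 to 735 ± 0.369 (adjusted p = 0.00372). The other leading genes that rose were Cep41 (2.08-fold), a ciliary and centrosomal gene, the immediate early gene Fos (2.02-fold), the interferon-induced gene Oasl2 (1.90-fold), the kinesin gene Kif6 (1.82-fold), and Emb and Ctsc (1.74-fold and 1.73-fold). Snhg11, a noncoding host of small nucleolar RNA, fell 2.69-fold, from 410 ± 36.2 to 152 ± 0.0148 (adjusted p = 0.015). The transcription cofactor gene Lbh fell 2.37-fold, from 476 ± 13.3 to 201 ± 11.5 (adjusted p = 0.00223). Kcne1, a potassium channel subunit of vestibular dark cells, fell 1.92-fold, from 221 ± 2.99 to 115 ± 3.33 (adjusted p = 0.00717). Tesc (2.03-fold), Inmt (1.86-fold), Churc1 (1.80-fold), Cracdl (1.79-fold) and the nuclear import receptor gene Ipo11 (1.78-fold) also fell. In limma, 24 probe sets were higher and 28 lower of 27083, 10 of them at least 2-fold, while 1777 had unadjusted p < 0.05. The number depends on the fit: with only the 4 arrays compared 3308 passed and with array weights by age 2825, each with all 52 of these, and with any 1 of the 4 arrays left out 2 to 4 passed. Without 1 array, Lbh alone of the 16 named genes stayed past the threshold, without the second control or the first cKO array, and the calls lost had adjusted p-values of 0.0524 (Lbh without the first control array) to 0.607.

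Among the gene lists at 2 months, that of G1/S and DNA replication was higher in cKO by its test. Rrm2, a subunit of ribonucleotide reductase, rose at least 1.47-fold (78.4 ± 2.01 to 139 ± 0.196, adjusted p = 0.0221) and the DNA primase gene Prim1 1.59-fold (193 ± 11.8 to 308 ± 29.9, adjusted p = 0.0392). With the pseudocount Rrm2 was at 0.43 log2 (adjusted p = 0.117), short of the threshold. Of the 30 members 26 had a positive log2 fold change (median 0.21), and 7 were higher and 1 lower when adjusted over the list alone. The list test by camera gave adjusted p = 3.68e-10 upward, and adjusted p = 0.00839 with an estimated correlation. The interferon list (10 genes) had a median of 0.32, with Oasl2 past the threshold and 5 higher adjusted over the list alone (adjusted p = 3.67e-06, and adjusted p = 0.0333 with an estimated correlation). For G2/M and mitosis (29 genes) no member passed, 7 had unadjusted p < 0.05 upward and 1 downward, and 2 were higher adjusted over the list alone. Its test gave adjusted p = 0.00649, and adjusted p = 0.141 with an estimated correlation, with Mki67 at 1.04 (adjusted p = 0.47, control signal below the 20th percentile) and Top2a below that percentile in both pools (adjusted p = 0.258). Kcne1 fell in the list of otoconia, dark cell, stria and melanocyte (15 genes, median -0.20), where 4 were lower adjusted over the list alone (adjusted p = 0.0154, and adjusted p = 0.125 with an estimated correlation). The Schwann cell and myelin list was lower with no member past the threshold (0 up and 2 down at unadjusted p < 0.05, median -0.12, adjusted p = 0.0486, and adjusted p = 0.141 with an estimated correlation). Fos alone passed in the immediate early and stress list (15 genes), whose median of -0.00129 and upward test (adjusted p = 0.333) differ in sign. Without 1 of the 4 arrays none of the 5 passing members kept its call (adjusted p = 0.102 to 0.551).

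The remaining lists had no member past the threshold at 2 months by limma, with these numbers at unadjusted p < 0.05. Of 26 hair cell genes 1 was higher and 2 lower, with Otof, needed for transmitter release, at -0.48 and Strc at -0.41 (median -0.04). The supporting cell and Notch list had 2 up (median 0.11, adjusted p = 0.0674, Sox2 at 0.45), the list of pocket proteins, E2Fs, cyclins D and CDK inhibitors 4 down (Cdkn1c at -0.43), and the p53 list 1 up and 2 down (Trp53inp1 at 0.73). For neuron there was 1 down (Ntrk2 at -0.36), for fibrocyte and mesenchyme 3 down (Lum at -0.49), for bone and cartilage 1 up and 2 down (Dmp1 at -0.79, 1 lower adjusted over the list alone) and for endothelium and pericyte 2 down (Flt1 at -0.41). Skeletal muscle had 1 up (Ttn at 0.25), erythroid 1 up (Car1 at 0.26), myeloid and lymphoid immune 2 up (C1qa at 0.48), brain 1 up (Aqp4 at 0.42) and oral and middle ear epithelium 0 (Ltf at -0.07).

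Sex-linked transcripts also differed between the pools, which bears on their makeup. Xist, transcribed from the inactive X chromosome, had a signal of 4739 ± 217 in control and 1765 ± 88.9 in cKO at 2 months (log2 fold change -1.42, adjusted p = 0.192). It was 4464 ± 2620 and 4545 ± 815 in the P6 utricle and 3682 ± 416 and 2684 ± 163 in the P6 cochlea (adjusted p = 0.854 and 0.506). No member of the sex chromosome list (2 genes) passed at 2 months by limma, and 1 was lower at unadjusted p < 0.05 and adjusted over the list alone. The probe set of the Y-linked gene Uty that stood for the gene did not pass (log2 fold change 0.20, 0.06 and -0.03). Another for Uty, looked up after its values were seen, had the smallest p-value of all at 2 months, with 63.0 ± 3.24 in control and 199 ± 8.02 in cKO (1.66, adjusted p = 3.71e-05). In the P6 utricle it was at 0.10 (adjusted p = 0.617) and in the P6 cochlea at 0.49 (adjusted p = 0.0171). The Y-linked gene Eif2s3y, below the filter and also looked up afterwards, had signals of 14.9 and 215 in control and cKO at 2 months, 73.1 and 262 in the P6 utricle and 80.1 and 370 in the P6 cochlea. Of the called probe sets placed on a chromosome, 1 of 48 at 2 months, 24 of 934 in the P6 utricle and 29 of 760 in the P6 cochlea lay on X or Y. Among all tested genes with a known chromosome the share was 3.07%.

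The P6 utricle of cKO mice was next compared with that of controls, and transcripts of DNA replication and cell division made up 7 of the 8 leading genes that rose. Rrm2 rose 7.81-fold, from 269 ± 34.6 to 2090 ± 57.5 (mean ± SD of 2 technical duplicates, SE 0.107 log2, adjusted p = 7.58e-07), and Prim1 5.02-fold, from 175 ± 10.8 to 876 ± 29.5 (adjusted p = 1.9e-06). The topoisomerase gene Top2a (4.77-fold), the helicase gene Mcm6 (4.63-fold), the cyclin gene Ccna2 (4.60-fold), the kinetochore gene Spc25 (4.59-fold) and the replication licensing gene Cdt1 (4.54-fold) rose likewise. Ttr, which encodes a thyroid hormone carrier made in abundance by choroid plexus, rose at least 5.22-fold (44.6 ± 0.776 to 518 ± 231, adjusted p = 1.48e-04), its control signal lying below the 20th percentile of the table. The developmental transcription factor gene Sox11 fell 11.1-fold, from 1113 ± 660 to 91.0 ± 3.86 (adjusted p = 6.86e-04), and the peripheral myelin gene Pmp2 3.60-fold, from 1582 ± 252 to 437 ± 4.09 (adjusted p = 1.13e-04). Sdc4 (4.02-fold), Mindy2 (2.89-fold), Synj2bp (2.89-fold), Gpm6b (2.78-fold), the proteoglycan gene Lum (2.72-fold) and the tubulin-modifying gene Ttll3 (2.70-fold) also fell. By limma 712 probe sets were higher and 391 lower, 225 of them at least 2-fold, and by gene 462 rose and 167 fell. The number was 76 with only the 4 arrays compared, 254 with only the P6 arrays, 566 with array weights by age, and 425 to 2492 with 1 array left out. With only the P6 arrays and a replicate block 1050 probe sets passed. Of the 16 named genes 10 passed with only the arrays compared (the others at adjusted p = 0.0525 to 0.144) and 13 with only the P6 arrays. Calls were lost for Sdc4, Gpm6b and Ttll3 without the second control array (adjusted p = 0.0918, 0.0819 and 0.0691), and for Sdc4 and Ttll3 without the first cKO array (0.137 and 0.113). Clip1, Mbp, Rbm39 and Smc4 had probe sets past the threshold in opposite directions.

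**Figure D1:**
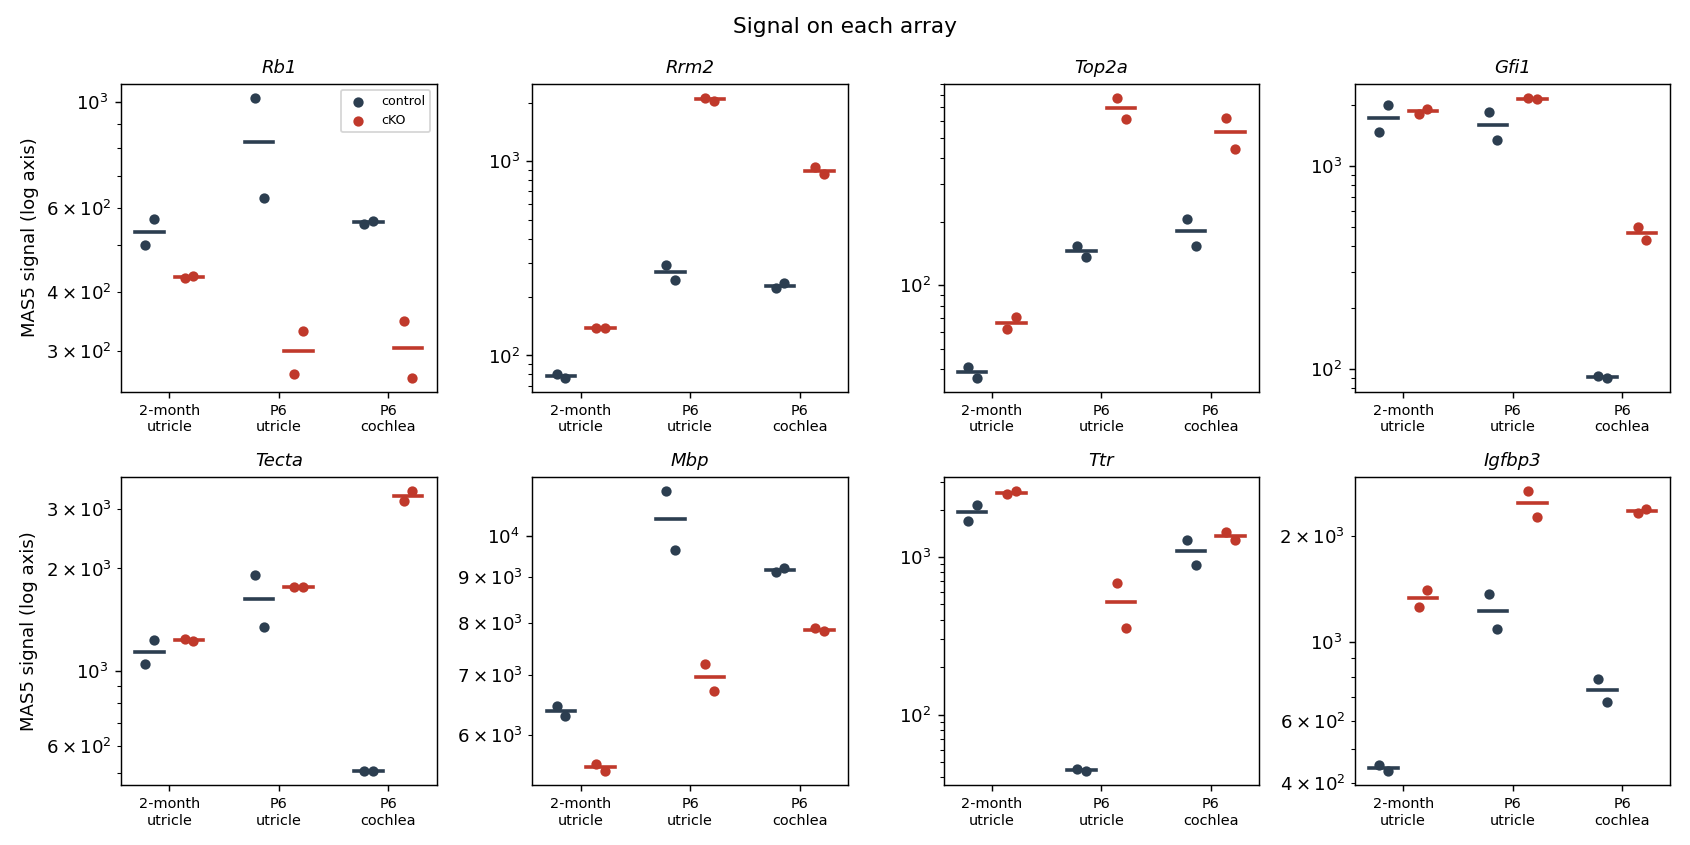
MAS5 signal (log axis) of Rb1, Rrm2, Top2a, Gfi1, Tecta, Mbp, Ttr and Igfbp3 on each array of the 3 settings, with points for technical duplicates, lines for their mean, control in dark and cKO in red. Rrm2 is higher in cKO in each setting (139, 2090 and 897), while Gfi1 and Tecta separate in the P6 cochlea (466 against 91.4 and 3271 against 507) and Ttr in the P6 utricle (518 against 44.6).

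By list, 21 of 30 genes of G1/S and DNA replication rose in the P6 utricle and none fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.01. The test gave adjusted p = 6.27e-32, and adjusted p = 3.10e-04 with an estimated correlation. Of 29 genes of G2/M and mitosis 17 rose (25 adjusted over the list alone, median 0.84), among them Top2a, Ccna2, Cdk1 (4.50-fold) and Mki67 (4.22-fold). The test gave adjusted p = 8.73e-21, and adjusted p = 0.00222 with an estimated correlation. In the list of pocket proteins, E2Fs, cyclins D and CDK inhibitors 7 of 24 rose, including Skp2 (2.28-fold), a ubiquitin ligase subunit that targets a CDK inhibitor, Tfdp1 (2.21-fold), a partner of E2F proteins, and Cdkn2d (2.11-fold). Rb1 fell there (11 up and 3 down adjusted over the list alone, adjusted p = 0.0594 for the list). The p53, DNA damage and apoptosis list had 4 of 24 higher (Rad54l, Atr, Gadd45g and Brca2, the first by 1.88-fold), also 4 adjusted over the list alone. The test gave adjusted p = 0.0359, and adjusted p = 0.0953 with an estimated correlation. Hair cell genes went mostly upward, with 7 of 26 higher and 1 lower (15 and 2 adjusted over the list alone, median 0.35). Those that rose included Pcdh15, a part of the tip link between stereocilia (3.38-fold), the calcium-binding gene Calb2 (1.91-fold), Lhx3 (1.90-fold) and Lhfpl5, a part of the mechanotransduction complex (1.90-fold), and the nicotinic receptor gene Chrna9 fell (-0.81). The hair cell test gave adjusted p = 0.00194, and adjusted p = 0.0953 with an estimated correlation. With only the arrays compared no hair cell gene, no member of the pocket protein list, 12 of the G1/S list and 8 of the G2/M list passed. Pcdh15 was lost without the second control array or either cKO array (adjusted p = 0.121, 0.122 and 0.127), Lhx3 without the first cKO array (0.0633), and Mki67 without the second control or the first cKO array (0.0501 and 0.0561).

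Genes of other cell types moved as well in the P6 utricle. Of 15 Schwann cell and myelin genes 5 fell (8 adjusted over the list alone, median -0.52), led by Ncmap (2.57-fold, 3007 ± 17.5 to 1172 ± 10.1, adjusted p = 1.63e-04), Mal (1.79-fold), Pmp22 (1.56-fold) and Mbp (1.5-fold). Their test gave adjusted p = 4.3e-08, and adjusted p = 0.00502 with an estimated correlation. In the fibrocyte and mesenchyme list (19 genes) Lum, Col1a1 (1.47-fold) and Sparc (1.33-fold) fell and Mgp rose (1.78-fold), with 1 up and 6 down adjusted over the list alone. That list was at adjusted p = 0.00919, and adjusted p = 0.0734 with an estimated correlation. Dmp1 (at least 1.73-fold) and Col11a1 (1.68-fold) fell in bone and cartilage (3 adjusted over the list alone, adjusted p = 0.0375, and adjusted p = 0.107 with an estimated correlation). In the supporting cell list Gjb6 (2.63-fold) and Gjb2 (1.70-fold), the connexin genes of the sensory epithelium and fibrocytes, fell and the Notch ligand gene Jag2 rose (1.51-fold). The median there was 0.00443 and the test pointed down (adjusted p = 0.11). Among the rest, Car12 rose (1.77-fold) and Kcne1 fell (1.51-fold) in the list of otoconia and dark cell, whose median of 0.00357 and downward test (adjusted p = 0.581) differ in sign. Nsg1 rose (2.07-fold) and Ntrk2 fell (1.37-fold) in neuron. The erythroid gene Alas2 fell (1.66-fold), the immune genes Lyz2 (1.56-fold) and C1qc (1.54-fold) rose. Of the brain list Cbln1 rose (1.59-fold) and Reln fell (1.73-fold). Fos and Dusp1 (1.94-fold each) and Jun (1.75-fold) rose in the immediate early list, with a median of -0.00228 and an upward test (adjusted p = 0.412). Ifit2 rose (1.90-fold) and Rsad2 fell (1.37-fold) among interferon genes. No member passed by limma in skeletal muscle (1 up at unadjusted p < 0.05, Acta1 at -0.57), endothelium (1 up and 2 down, Egfl7 at -0.47), oral epithelium (0, Krt4 at -0.08) or sex chromosome (0). Of the 47 passing members named for all lists here, 20 kept their call with every array left out in turn (lost ones at adjusted p = 0.05 to 0.204), 11 with only the arrays compared and 22 with only the P6 arrays. Mal was at 0.0741, 0.137 and 0.0811 without the first control, first cKO or second cKO array.

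In the P6 cochlea, the 8 leading genes that rose included Gfi1 and Lhfpl5 of the hair cell list and Tecta of the supporting cell list. Skor1, a transcriptional corepressor gene, rose at least 5.1-fold, from 41.8 ± 2.49 to 346 ± 66.7 (mean ± SD of 2 technical duplicates, SE 0.144 log2, adjusted p = 2.09e-05). Tecta, which encodes a protein of the tectorial and otolithic membranes, rose 6.45-fold, from 507 ± 0.517 to 3271 ± 164 (adjusted p = 3.45e-05). The hair cell transcription factor gene Gfi1 rose at least 4.94-fold, from 91.4 ± 1.29 to 466 ± 49.3 (adjusted p = 1.08e-04), and Lhfpl5 4.64-fold, from 204 ± 28.7 to 946 ± 139 (adjusted p = 7.80e-05). The matrix gene Tnc (5.69-fold), Smpx (4.78-fold), the neuropeptide gene Grp (4.40-fold) and Agr3 (at least 3.04-fold) rose too. The control signals of Skor1, Gfi1 and Agr3 lay below the 20th percentile of their tables. In control tissue Skor1, Gfi1 and Agr3 were lower in the cochlea than in the utricle. Of 68 genes at least 4-fold higher on the first control utricle array than on the first control cochlea array, and higher in cKO utricle than on the second control cochlea array, 32 rose in the cKO cochlea (median 0.69 log2). Of 40 picked likewise for the cochlea 12 fell there (median -0.58). In the mirror case, of the 40 cochlea-enriched genes 4 rose in the cKO utricle (median -0.05). This comparison was chosen after the values were seen, and the control signal that picks the genes also enters their fold change. Sox11 fell 8.48-fold, from 839 ± 217 to 97.2 ± 0.0649 (adjusted p = 0.00104), though its probe sets past the threshold had opposite directions. Emilin2, a matrix gene, fell 3.56-fold, from 3260 ± 13.5 to 937 ± 283 (adjusted p = 5.52e-04), and the thyroid hormone transporter gene Slco1c1 3.41-fold (adjusted p = 1.08e-04). Itgbl1 (3.33-fold), Vit (3.01-fold), the secretogranin gene Scg2 (2.82-fold), the cartilage gene Ucma (2.75-fold) and Dnase1 (2.65-fold) fell as well. By limma 590 probe sets were higher and 292 lower, 197 of them at least 2-fold, and by gene 348 rose and 174 fell. The number was 177 with only the 4 arrays compared, 228 with only the P6 arrays, 459 with array weights by age, and 239 to 766 with 1 array left out. The share that was higher, 66.9%, hung on the cKO arrays: it was 44.4% without the first and 77.4% without the second. Of the 16 named genes, 15 kept their call with each array left out, and Smpx lost it without the second control array (adjusted p = 0.0664). With only the arrays compared 12 of the 16 passed, the others at adjusted p = 0.0517 to 0.0928. With only the P6 arrays and a replicate block 780 probe sets passed.

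By list, 13 of 26 hair cell genes rose in the P6 cochlea and none fell (18 and 0 adjusted over the list alone, median 0.61). Besides Gfi1 and Lhfpl5 these included Atoh1, the transcription factor gene that drives hair cell fate (129 ± 1.64 to 378 ± 20.7, 2.92-fold, adjusted p = 3.28e-05), and Rbm24 (2.88-fold). The test gave adjusted p = 1.03e-12, and adjusted p = 0.00546 with an estimated correlation. Of the 24 genes of supporting cell and Notch 9 rose (10 up and 1 down adjusted over the list alone, median 0.29), with Tecta, Cyp26b1 (2.81-fold), Otog (2.63-fold) and Sox2 (2.52-fold) in front (adjusted p = 7.56e-04, and adjusted p = 0.0258 with an estimated correlation). Transcripts of G1/S and DNA replication rose in 19 of 30 (21 adjusted over the list alone), led by Rrm2 (3.91-fold, 229 ± 10 to 897 ± 47.7), the ligase gene Lig1 (3.37-fold), Prim1 (3.08-fold) and Dut (2.92-fold). The test gave adjusted p = 3.87e-23, and adjusted p = 8.00e-04 with an estimated correlation. For G2/M and mitosis 12 of 29 rose (19 adjusted over the list alone, median 0.59), including Mki67 (3.54-fold), Top2a (2.93-fold), Ccna2 (2.79-fold) and Cdk1 (2.33-fold). The test gave adjusted p = 2.04e-13, and adjusted p = 0.00546 with an estimated correlation. Of the p53 list Btg2 (1.76-fold), Rad54l (1.74-fold) and Brca2 (1.38-fold) rose (adjusted p = 0.00635, and adjusted p = 0.0407 with an estimated correlation). E2f8 (1.5-fold) and E2f7 (1.43-fold) rose in the pocket protein list, and the cyclin gene Ccnd2 fell 2.33-fold, from 2676 ± 290 to 1144 ± 23.8 (adjusted p = 3.83e-04). With only the arrays compared 8 hair cell genes, 4 of the supporting cell list, 10 of G1/S and 8 of G2/M passed. Mki67 was lost without either control array or the first cKO array (adjusted p = 0.0573, 0.131 and 0.0709), Sox2 without the second control or first cKO array (0.118 and 0.0602), and E2f8, Rad54l and Brca2 without any 1 of the 4 arrays.

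Among the genes that fell in the cKO cochlea were members of the fibrocyte and the bone and cartilage lists. The fibrocyte gene Coch fell 2.30-fold, from 4703 ± 533 to 2111 ± 758 (adjusted p = 0.0225). Tbx18 (1.66-fold) and Dcn (1.61-fold) fell too among 19 fibrocyte and mesenchyme genes (1 up and 8 down adjusted over the list alone, median -0.32). The list was at adjusted p = 0.00209, and adjusted p = 0.0326 with an estimated correlation. The melanocyte gene Dct (2.49-fold), Car12 (2.30-fold) and the anion exchanger gene Slc26a4 (1.96-fold) fell in the list of otoconia and stria (4 adjusted over the list alone, adjusted p = 0.148). Col11a1 fell (1.59-fold) in bone and cartilage (median -0.27, adjusted p = 0.00597, and adjusted p = 0.0407 with an estimated correlation). S100b (1.42-fold) and Pmp22 (1.26-fold) fell in Schwann cell and myelin (3 adjusted over the list alone, adjusted p = 0.00209, and adjusted p = 0.0326 with an estimated correlation). Among neuron genes Snap25 (1.76-fold) and Ntrk2 (1.53-fold) fell and the transcription factor gene Isl1, present in sensory progenitors as well, rose (2.27-fold). Cbln1 of the brain list rose 3.01-fold. The erythroid list had no member past the threshold by limma (2 down at unadjusted p < 0.05, Car2 at -0.79), with adjusted p = 0.0187, and adjusted p = 0.0701 with an estimated correlation. No member passed in immediate early and stress (1 up and 1 down at unadjusted p < 0.05, Ccn1 at -0.52), or interferon (1 up and 1 down, Ifit2 at 0.55). Nor did any in myeloid and lymphoid immune (1 up, Lyz2 at 0.33), endothelium (1 down, Egfl7 at -0.40), oral epithelium (0, Sprr1a at 0.21) or sex chromosome (0). Skeletal muscle also had none (1 up and 2 down, Eno3 at 0.39), and its median of -0.02 and upward test (adjusted p = 0.646) differ in sign. Adjusted over the list alone, 1 was lower in each of erythroid, immediate early, interferon and skeletal muscle, and 1 higher in skeletal muscle. Of the 35 passing members named for all lists here 19 kept their call with every array left out in turn (lost ones at adjusted p = 0.0552 to 0.297), and 18 with only the arrays compared. Coch was lost without either control or the second cKO array (0.167, 0.0966 and 0.115), and Tbx18 and Dcn without any 1 of the 4.

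**Figure D2:**
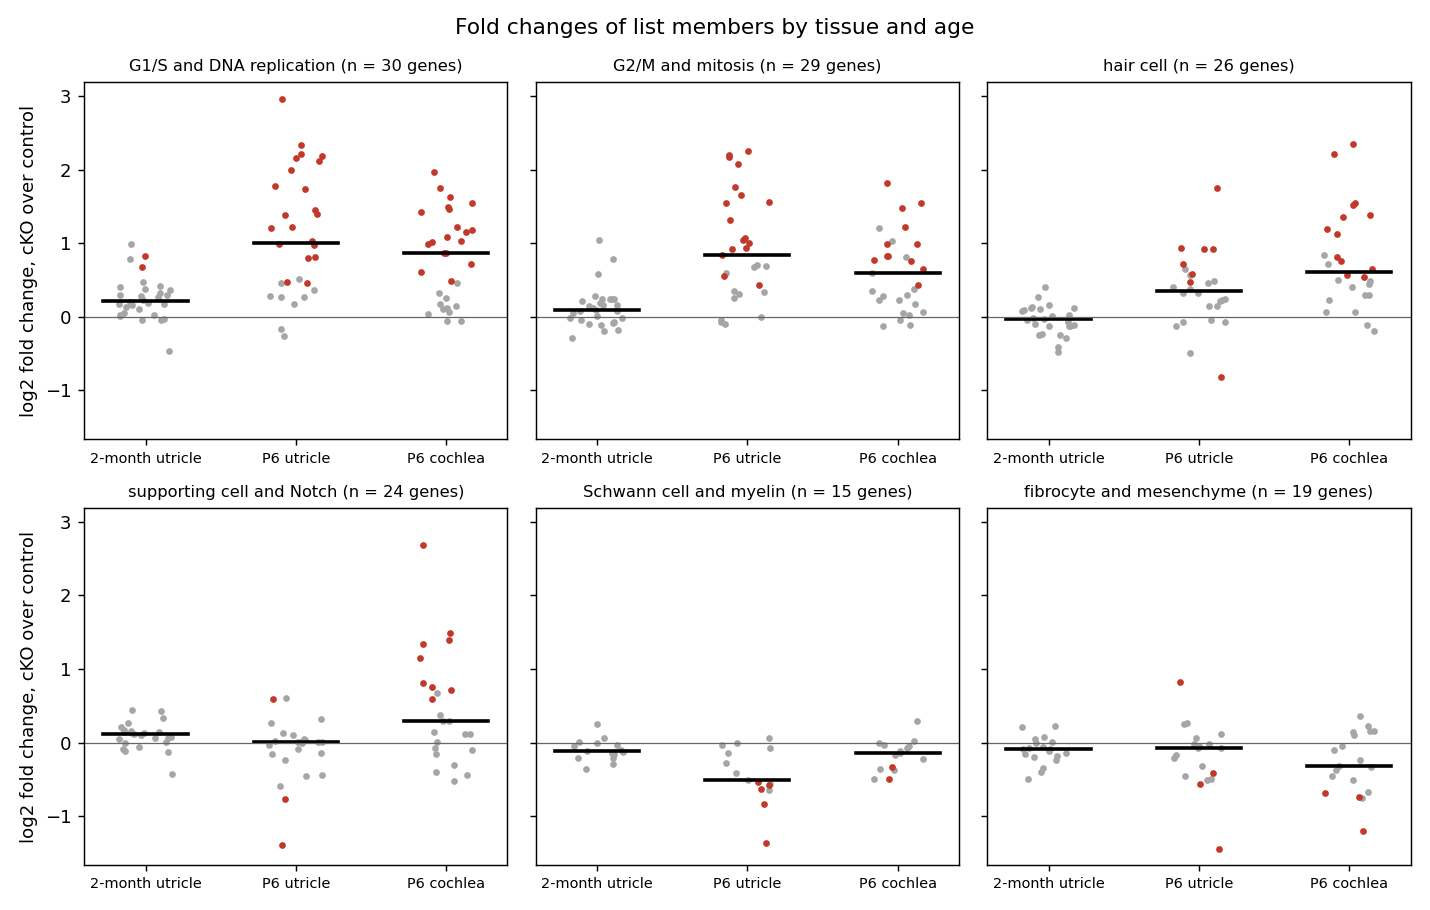
Log2 fold change of cKO over control for the members of 6 gene lists in the 3 settings, 1 point per gene, red where adjusted p < 0.05, with a black line at the median. The G1/S median goes from 0.21 at 2 months to 1.01 in the P6 utricle and the hair cell median from 0.35 in the P6 utricle to 0.61 in the P6 cochlea, while the Schwann cell median is -0.52 in the P6 utricle.

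The effects in the P6 utricle and P6 cochlea overlapped. Of the genes past the threshold 147 rose in each tissue, against 12 if the calls were independent, and 27 fell in each, against 2.16. Against these, 2 rose in the utricle and fell in the cochlea (5.98 if independent), and 4 did the reverse (4.32 if independent). Over 13450 genes the log2 fold changes correlated at r = 0.473 (rank correlation 0.403), a value over genes measured in 2 pairs of pools and thus not over independent samples. Whether both tissues came from the same animals is not given in the labels, so shared animals could enter this overlap. Igfbp3 (1.59, 1.01 and 1.68 log2), Prim1 and Rrm2 rose in all 3 settings, though the 2-month call for Rrm2 was lost with the pseudocount (adjusted p = 0.117). Ipo11 (-0.83, -0.65 and -0.76) and Lbh (-1.24, -0.83 and -0.65) fell in all 3. Between the 2-month and the P6 utricle 5 genes rose and 6 fell in both (0.515 and 0.223 if independent), and 1 and 4 went in opposite directions (0.186 and 0.618 if independent). Calls share 1 spread per probe set and are not independent, so these values are no level for the absence of a shared effect. The 2-month effect correlated with that in the P6 utricle at 0.0279 and in the P6 cochlea at 0.0519.

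**Figure D3:**
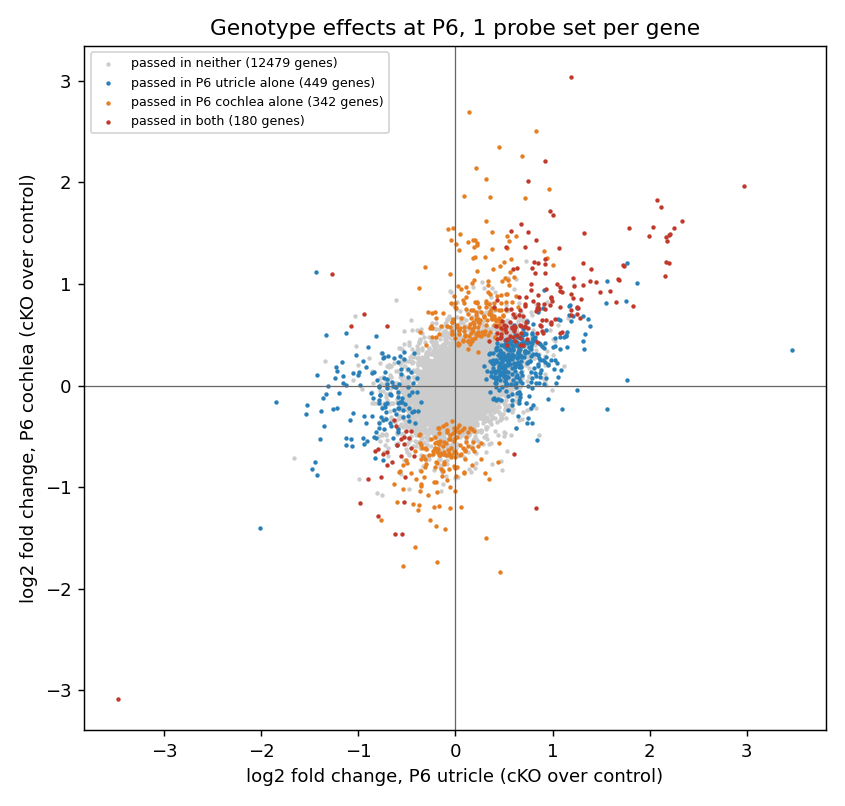
Log2 fold change of cKO over control in the P6 utricle (horizontal) and the P6 cochlea (vertical), 1 point per gene, coloured by whether the adjusted p passed 0.05 in neither tissue (12479), the utricle alone (449), the cochlea alone (342) or both (180). Most genes past the threshold in both tissues lie in the upper right or lower left.

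Whether the genotype effect differed between P6 utricle and P6 cochlea was tested directly, as the effect in the utricle minus that in the cochlea. Ttr (difference 3.11 log2, SE 0.391, adjusted p = 0.0108), Emilin2 (2.29, adjusted p = 0.00309), the carbonic anhydrase gene Car12 (2.02, adjusted p = 0.0128) and Scg2 (1.81, adjusted p = 0.0216) were higher by this measure. For Ttr the control utricle signal lay below the 20th percentile, and with the pseudocount the difference was 1.77 (adjusted p = 0.0594), short of the threshold. Tecta (-2.55, SE 0.228, adjusted p = 0.00216), Ttll3 (-2.55, adjusted p = 0.0216), the immunoglobulin gene Ighm (-2.37, adjusted p = 0.00216) and Grp (-1.92, adjusted p = 0.0122) were lower. Of these, Emilin2 and Scg2 fell in the cochlea, Tecta and Grp rose there, Ighm fell in the utricle (-1.27) and rose in the cochlea (1.10), and Car12 rose in the utricle (0.82) and fell in the cochlea (-1.20). Of the supporting cell list Tecta, Otog and Cyp26b1 were lower, that is more raised in the cochlea (1 up and 11 down adjusted over the list alone, median -0.51, adjusted p = 1.31e-08, and adjusted p = 0.00842 with an estimated correlation). For the hair cell list 6 members were lower, such as Gfi1 (1 up and 8 down adjusted over the list alone, median -0.31, adjusted p = 2.19e-06, and adjusted p = 0.0347 with an estimated correlation). G1/S (1 member, Rrm2, median 0.35) and G2/M (1 member, the spindle gene Nusap1, named after its values were seen, median 0.25) leaned to the utricle. Their tests gave adjusted p = 1.82e-06 and 8.29e-06, and adjusted p = 0.016 and 0.0384 with an estimated correlation. The pocket protein list was at adjusted p = 0.0213, and adjusted p = 0.0759 with an estimated correlation. The Schwann cell list was at adjusted p = 0.00467, and adjusted p = 0.0508 with an estimated correlation. By limma 204 probe sets passed, 60 higher and 144 lower, but 7 with only the arrays compared, 107 with array weights by age and 36 to 594 with 1 array left out. The share that was higher, 29.4%, was 51.7% without the first cKO cochlea array and 15% without the second. Tecta, Emilin2 and Ighm kept their calls without any 1 array, while Ttr lost its own without the first cochlea control array (adjusted p = 0.0605) and Car12, Scg2, Ttll3 and Grp lost theirs without 1 or more arrays (0.0522 to 0.122). With only the arrays compared Tecta and Ighm alone of the 8 passed, and the others were at adjusted p = 0.0619 to 0.176.

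The effect also differed between the 2-month and the P6 utricle, taken as the 2-month effect minus the P6 effect. Sox11 (4.10, SE 0.457, adjusted p = 0.00403), Kif6 (2.17, adjusted p = 1.59e-04), Mindy2 (1.96, adjusted p = 0.00167) and Gpm6b (1.92, adjusted p = 0.0398) were higher by this measure. Ttr (-3.03, adjusted p = 0.00533), Erdr1 (-2.34, adjusted p = 0.00298), Rrm2 (-2.14, SE 0.151, adjusted p = 3.20e-04) and Spc25 (-2.01, adjusted p = 2.19e-04) were lower. The size for Ttr rests on a P6 control signal below the 20th percentile (-1.68 with the pseudocount, adjusted p = 0.0376). Of G1/S and DNA replication 16 of 30 genes were lower (21 adjusted over the list alone, median -0.85) and of G2/M and mitosis 11 of 29 (18 adjusted over the list alone, median -0.77), which put the larger rise of cell cycle transcripts at P6. Their tests gave adjusted p = 1.05e-22 and 2.26e-15, and adjusted p = 8.45e-04 and 0.00521 with an estimated correlation. Hair cell genes were lower in 4 (1 up and 10 down adjusted over the list alone, median -0.39) and the pocket protein list in 5 (1 up and 8 down). Their tests gave adjusted p = 0.00101 and 0.0136, and adjusted p = 0.0625 for each with an estimated correlation. The Schwann cell list was higher (4 adjusted over the list alone, median 0.35, adjusted p = 1.71e-04, and adjusted p = 0.0258 with an estimated correlation). So were the supporting cell list (adjusted p = 0.00778, and adjusted p = 0.0552 with an estimated correlation) and the interferon list (adjusted p = 3.78e-04, and adjusted p = 0.053 with an estimated correlation). By limma 138 probe sets were higher and 325 lower, 882 in total passed with array weights by age, and 74 to 1034 with 1 array left out. Gpm6b was lost without any 2-month array or the second P6 control array (adjusted p = 0.0882 to 0.166), and the other named genes kept their calls.

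The control utricle at 2 months was then set against that at P6, as a description of age. The 5 leading genes that were lower at 2 months included 4 collagen genes. Col2a1 of cartilage was 23.4-fold lower (6742 ± 1314 at P6 and 285 ± 7.83 at 2 months, adjusted p = 7.87e-07), Col3a1 17.0-fold (adjusted p = 1.61e-07), Col4a1 11-fold, Col9a3 10.2-fold and the growth-associated gene Nrep 8.68-fold. Ttr was at least 20.2-fold higher at 2 months (44.6 ± 0.776 and 1917 ± 322, adjusted p = 2.36e-06), Etnppl 15.3-fold, Rnase1 8.02-fold, the metallothionein gene Mt2 7.71-fold and the anion exchanger gene Slc26a7 7.52-fold. Of 19 fibrocyte and mesenchyme genes 12 were lower and 2 higher, with Col1a2 (4.58-fold), Col5a1 (3.69-fold) and Postn (3.24-fold) beside Col3a1 (adjusted p = 4.3e-06, and adjusted p = 0.0234 with an estimated correlation). Of G2/M and mitosis 8 were lower, such as Top2a (at least 1.54-fold) and Mki67 (at least 2.69-fold), and 2 higher (adjusted p = 0.0119, and adjusted p = 0.247 with an estimated correlation). The cyclin D gene Ccnd1 (3.10-fold) and the kinase gene Cdk6 (2.81-fold) were lower. Hair cell genes were higher in 11 of 26, including Calb2 (2.38-fold), Lhfpl5 (2.05-fold) and the calcium pump gene Atp2b2 (1.83-fold), with adjusted p = 0.0622. The antigen presentation gene H2-Aa (3.83-fold) and the heat shock gene Hspa1b (4.16-fold) were higher, and Fabp7 (5.44-fold) and the otoconial gene Oc90 (4.94-fold) lower. By limma 2388 probe sets were higher and 2192 lower, 849 of them at least 2-fold, and 2291 passed with only the arrays compared and 1846 to 5682 with 1 array left out. The share that was higher, 52.1%, was under 50% without some of these arrays (48% without the second 2-month array). Each age is 1 pool, so that pool and age are not separable.

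Control cochlea was set against control utricle at P6 in the same manner. Epyc, a proteoglycan gene of the cochlear epithelium, was 52.7-fold higher in the cochlea (142 ± 8.88 in the utricle and 7468 ± 86.0 in the cochlea, adjusted p = 1.04e-07), Ttr at least 11.3-fold, Scg2 at least 20.7-fold, Emilin2 16.5-fold and Crym, which encodes a thyroid hormone binding protein, 13.8-fold. Skor1 was at least 18.6-fold lower (1253 ± 149 and 41.8 ± 2.49, adjusted p = 1.96e-07), Tnfaip2 at least 12-fold, Gfi1 at least 16.6-fold, Agr3 at least 11.3-fold and Ttll3 at least 8.85-fold. For these 5, and for Ttr and Scg2, the dimmer signal lay below the 20th percentile of its table, so that the folds are bounds without an order. Of 26 hair cell genes 17 were lower in the cochlea and 1 higher (median -0.77), with Ush1c (6.55-fold), Otof (5.11-fold) and Fscn2 (4.29-fold) after Gfi1 (adjusted p = 9.81e-10, and adjusted p = 0.015 with an estimated correlation). Of 18 neuron genes 13 were higher (median 0.91), led by Stmn2 (9.94-fold), Snap25 (5.25-fold) and Stmn3 (4.52-fold). The list was at adjusted p = 1.41e-09, and adjusted p = 0.015 with an estimated correlation. Fibrocyte and mesenchyme genes (10 of 19, Lum 4.21-fold, Otos 4.13-fold) and bone and cartilage genes (8 of 12, Cnmd 5.54-fold, Dmp1 5.39-fold) were also higher. These lists were at adjusted p = 3.52e-05 and 9.69e-04, and adjusted p = 0.0152 and 0.0353 with an estimated correlation. Supporting cell genes were lower in 11 of 24 (Otog 8.07-fold, Gjb6 3.61-fold) and higher in 2 (Tectb 3.31-fold). That list was at adjusted p = 0.00461, and adjusted p = 0.0416 with an estimated correlation. By limma 1868 probe sets were higher and 2576 lower, 959 of them at least 2-fold, and 1781 passed with only the arrays compared and 2136 to 6240 with 1 array left out. The share that was higher, 42%, depends on the scaling: it was 51.3% with arrays centred on their medians and 47.5% with quantile normalization, so that neither direction prevailed throughout.

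The genotype effect common to the 3 pairs of pools was tested with the pair as the unit (n = 3 pairs). The labels do not say whether the P6 utricle and P6 cochlea pools came from the same animals, so the pairs may not be independent. Igfbp3 had the smallest p-value (mean log2 fold change 1.43, SE 0.156, unadjusted p = 8.65e-05, adjusted p = 0.429), followed upward by Mki67 (1.65), Runx1t1 (0.99), the nucleoside kinase gene Dck (0.76) and Mcm6 (1.56). Ipo11 (-0.75, SE 0.102, adjusted p = 0.429), Ctxn3 (-0.71), Lbh (-0.91), Paqr6 (-0.41) and Dmp1 (-0.81) were lowest by p. By limma 0 of 27083 probe sets passed, with 2168 at unadjusted p < 0.05 and a smallest adjusted p of 0.429 on type a and 0.685 on type b. G1/S and DNA replication had a median of 0.73 with 18 genes higher adjusted over the list alone, and G2/M and mitosis 0.46 with 12 (adjusted p = 3.23e-19 and 1.62e-12, and adjusted p = 0.391 for each with an estimated correlation). Hair cell genes had a median of 0.32 (adjusted p = 1.47e-04, and adjusted p = 0.431 with an estimated correlation). Schwann cell genes were at -0.28 and fibrocyte genes at -0.19 (adjusted p = 3.07e-06 and 2.28e-04, and adjusted p = 0.391 for each with an estimated correlation). Without the 2-month pair 79 probe sets passed. With the pool as a random block 173 passed, but that fit took arrays as its units. Its correlation within pools was 0.106 (type a) and -0.00451 (type b). Duplicates thus counted nearly as separate pools, and 173 is no count with the pool as the unit.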

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

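The tests of hair cell genes against vestibular tissue, against hair cells alone and against tissue of the same makeup, the test of RNA integrity between pools, and the stricter limits on the sex test and on the mixing test of cell cycle genes, were chosen only after the results were seen, and the test within pools was then narrowed to labelling and hybridisation. Results stand here because a test of the difference between groups passed the threshold, or because a signal above control was present in a probe set that no comparison used. The effect in the P6 utricle minus that in the P6 cochlea was positive, in log2, for Ttr (3.11), Emilin2 (2.29), Car12 (2.02), Scg2 (1.81), Itgbl1 (1.55), Dnase1 (1.30), Slco1c1 (1.23), Rrm2 (1.0) and Spc25 (0.99). It was negative for Tecta (-2.55), Ttll3 (-2.55), Ighm (-2.37), Grp (-1.92), Gfi1 (-1.89), Skor1 (-1.85), Agr3 (-1.72), Pmp2 (-1.68), Synj2bp (-1.34), Kif6 (-1.30), Lhfpl5 (-1.29) and Mindy2 (-1.25). The effect at 2 months minus that at P6 in the utricle was positive for Sox11 (4.10), Kif6 (2.17), Mindy2 (1.96), Gpm6b (1.92), Synj2bp (1.80), Pmp2 (1.77), Cep41 (1.51), Pomc (1.38), Ighm (1.22) and Ctsc (0.92). It was negative for Ttr (-3.03), Erdr1 (-2.34), Rrm2 (-2.14), Spc25 (-2.01), Ccna2 (-1.96), Cdt1 (-1.76), Cracdl (-1.69), Prim1 (-1.66), Top2a (-1.47), Mcm6 (-1.23), Snhg11 (-1.23), Lhfpl5 (-1.18), Churc1 (-1.08) and Tesc (-0.79). Of the differences between the P6 tissues, those of Ttr, Scg2, Ttll3, Gfi1, Skor1 and Agr3 include a pool below the 20th percentile of signal, as do those between the ages of Ttr, Rrm2, Spc25, Ccna2, Top2a and Snhg11, so that their sizes are uncertain. Eif2s3y, a Y-linked gene below the filter, had signals of 215 (2-month utricle), 262 (P6 utricle) and 370 (P6 cochlea) in the cKO pools, above the control pools of the same settings.

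The first pattern weighed was the rise of cell cycle transcripts in the cKO pools at P6. Within a P6 pool, the array with the higher actin ratio had the list members higher by a median of only 0.0219 log2, against genotype medians of 0.931 in the utricle and 0.718 in the cochlea. This argues only against a labelling or hybridisation effect that moves with this ratio between the arrays of a pool. The array with the higher ratio was the first in every P6 pool. A labelling or hybridisation difference between cKO and control pools was therefore not tested. RNA integrity of the pools stays open, since duplicates share their RNA and the ratio was higher in the cKO pools by 0.348 log2 or more. The difference between duplicates was larger, up to 1.09, but it had the same direction in every P6 pool and is no random spread. Between arrays of the same number, the cKO ratio was higher than the control ratio in both P6 tissues and on both array types. For the cochlea alone, a mix of control cochlea with cKO utricle, at the share of 11.2% given by other utricle-enriched genes, left the cell cycle genes a median of 0.446 log2 above it, against 0.72 observed. This met the limit set before the result was seen for arguing against such a mix, a median of at least 0.36. The limit added afterwards asked the same at the upper-quartile share, where the median was 0.338, with 51 of 59 genes above the mix. Residuals at 11.2% spread widely (quartiles 0.132 and 0.843). Vestibular tissue of cKO animals in this pool therefore stays open for part of the pattern. So does an effect of the genotype on dividing cells, the explanation that the design names.

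The second pattern was the rise of hair cell genes in the cKO cochlea, where utricle-enriched genes outside the hair cell and cell cycle lists had a median share of utricle signal of 11.2%, against 22.6% for the 4 utricle-enriched hair cell genes, and Skor1 and Agr3 rose with Gfi1, which could come from vestibular tissue in the pool. A mix of control cochlea with cKO utricle at 11.2% left the hair cell list a median of 0.361 log2 above it (23 of 26 genes above), and at 19.6%, the upper quartile, 0.231, against 0.609 observed, and Tecta was higher in the cKO cochlea (3271) than on either cKO utricle array (1762 and 1758), so that such a mix alone does not give its signal. More hair cells without any other change were weighed as well. The utricle-enriched genes of the supporting cell and otoconia lists were only 2, Otog (22.9%) and Mlana (-3.32%). Their median share of 9.81% therefore decides nothing. Of the 24 tested genes of the supporting cell and Notch list, however, 9 rose past the threshold in this pool and 0 fell. This argues against hair cells as the only change, while more hair cells beside other changes stay open. Against tissue of the same makeup as the utricle pools as the whole cause, 34 of 64 utricle-enriched genes lay below such a mix by more than 2 standard errors, though at the lower-quartile share of 17% the number was 29. The explanations left cannot be told apart here, since the share rests on few genes and 1 pool (cochlea-enriched genes in the cKO utricle had a median share of 0.76%), and an effect of the genotype on hair cells was not tested apart from them. The other utricle-enriched genes were set apart by the hair cell list alone. Whether hair cells transcribe some of them, such as Smpx (23.1%) or Myo3b (45.4%), was not tested. Their share therefore need not read vestibular tissue other than hair cells.

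The third pattern was the set of calls at 2 months, where the Y-linked gene Uty was higher in cKO and the signal of Xist lower. Of the 33 called genes with a known chromosome 0 lay on X or Y, against 3.07% of tested genes. Of the called probe sets 2.08% did, a unit that the limit did not name. Both lay under the limit of 10% of called genes, set before the result was seen for arguing against a different share of females and males. That limit was wrong, because genes that depend on sex need not lie on X or Y, and the call for Uty itself shows pools of different makeup. A sex difference between the pools therefore could account for an unknown part of these calls, and the genotype for the rest, with nothing in the design to separate them. The P6 calls carry the same doubt, since Eif2s3y was higher in the cKO pools there as well and Uty passed in the P6 cochlea (adjusted p = 0.0171).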

How the results depend on the processing

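The fits of only the P6 arrays, the array weights by age, and the fits of the arrays compared with a block were tests chosen only after the data were seen. Values of named genes under the alternatives kept direction and side of the threshold in 2787 cases, fell short of it in 379, newly passed in 134, moved in 8 and reversed in 0. Quantile normalization, median centring, no filter, the pseudocount and no intensity trend left every total within 1.5 times, and the list tests gave 20 to 27 calls against 21, but 13 with an estimated correlation. With the filter at the 60th percentile 23 probe sets passed at 2 months, against 52, and fewer were tested. A fold of at least 2, stricter by construction, left 10 at 2 months, 225 in the P6 utricle, 197 in the P6 cochlea, 127 for the difference between these tissues, 242 for that between the ages, 849 for age and 959 for tissue. With only the arrays compared, 3308, 76 and 177 passed in the 3 settings, 7 for the difference between tissues, 2291 for age and 1781 for tissue; array weights by age gave 2825, 566 and 459, and 107 and 882 for the differences. Only the P6 arrays gave 254 and 228. Fits of fewer arrays change the shared spread and the residual degrees of freedom together, and their parts were not tested. With each array left out in turn, the lone array of its group assumed to vary like the other groups, the totals ranged over 2 to 4, 425 to 2492 and 239 to 766 in the 3 settings. They ranged over 36 to 594 and 74 to 1034 for the differences, 1846 to 5682 for age and 2136 to 6240 for tissue. The cause of these ranges was not tested. Signal over background limits dim genes, for which the absence of a call says little.

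The main fit did not pair samples by replicate number, a choice made before the data were examined. Deviations of the same number correlated at 0.0834 (type a) and -0.158 (type b) at 2 months, and between the P6 pools from 0.299 to 0.675 (type a) and from -0.0899 to 0.579 (type b). The P6 arrays of 1 number thus deviated together on type a, and on type b except between the cKO utricle and cKO cochlea pools (-0.0899). Fits at P6 without the block leave this shared deviation in the spread. With the number as a replicate block the totals were 44, 1407 and 1091 in the 3 settings, 272 and 593 for the differences, 5271 for age and 5162 for tissue. For pool pairs the block was added to the fit of arrays with the pool as a random block, which gave 94 with it and 173 without. With only the P6 arrays and a replicate block, 1050, 780 and 115 passed (utricle, cochlea and their difference), against 254, 228 and 7 without the block. With only the 2-month arrays and a replicate block 4046 passed. Rb1 passed with the block in the P6 cochlea (adjusted p = 0.0461) and, with only the 2-month arrays and the block, at 2 months (0.0186). With the numbers crossed, 3925 passed at 2 months.

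Over pool pairs, leaving out a pair gave 0 to 79 probe sets and the pool as a random block 173, with a correlation within pools of 0.106 (type a) and -0.00451 (type b). The random-block fit took arrays as units and, at these correlations, counted duplicates nearly as separate pools. Of the 10 splits of the 6 pools 10 gave as many adjusted calls (real 0, highest other 0) and 4 as many at unadjusted p < 0.05 (real 2168, highest other 2331), and 10 splits are too few for a share under 0.05. The splits kept the block, so each still set cKO against control within a pair of pools. None of them gives a level without a genotype effect.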

Other observations

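The probe sets in this part were chosen only after their values were seen: each passed the threshold where the brighter one that stood for its gene did not. Several belong to cell division. Cenpf, a kinetochore gene, was higher in cKO by 2.06 log2 in the P6 utricle (adjusted p = 5.93e-06) and 1.56 in the P6 cochlea (adjusted p = 5.23e-05), where the brighter probe set was at -0.09 and -0.11. Probe sets of Cdca8, a subunit of the chromosomal passenger complex, were at 2.00 and 2.33 in the P6 utricle and 1.12 and 1.55 in the P6 cochlea. Bub1b of the spindle checkpoint was at 0.85 in the P6 cochlea (adjusted p = 0.00425), and the replicative helicase gene Mcm2 at 0.71 in the 2-month utricle (adjusted p = 0.015). Among regulators of the G1/S step, E2f1 was at 0.79 (adjusted p = 0.018), Cdk4 at 0.56 (adjusted p = 0.0299) and Ccnd1 at -0.69 (adjusted p = 0.0203) in the P6 utricle, and Skp2 at 0.89 in the P6 cochlea (adjusted p = 0.00582).

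Other such probe sets belonged to several lists. In the P6 cochlea Col9a1 was at -1.0 (adjusted p = 0.0425), Ogn at -0.96 (adjusted p = 0.0058) and the Notch ligand gene Jag1 at 0.92 (adjusted p = 0.0213, brighter probe set -0.16). Mbp was at 0.68 there (adjusted p = 0.0184), opposite in sign to its brighter probe set (-0.22). At 2 months Dmp1 was at -0.89 (adjusted p = 0.00524) and Car12 at 1.46 (adjusted p = 0.00148). No explanation of these differences between probe sets of 1 gene was tested.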
